A study of Mus musculus with 9 samples.

How the data were processed

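RNA was sequenced from 9 libraries of mouse osteoclasts grown from bone marrow, in 3 groups of 3 libraries named WT_CTR, KO_CTR and KO_4OI after the titles of the samples, which also give the replicate numbers. Per the labels' protocols, RNA was taken on day 3, 4-octyl-itaconate was added at 50 µM on day 1 of culture, and libraries were made from total RNA with a NEBNext Ultra RNA kit. The labels do not say whether the replicates of a group came from separate mice, so p-values measure the spread between these libraries, which may be partly technical.

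The deposited table holds raw read counts per Ensembl gene, whole numbers with 1 column per library and no pooled column. Per the submitters' processing notes, fastp, STAR and HTSeq 0.6.1 were used with the mouse build mm10. The versions of fastp and STAR, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart. Reads that match several places equally well may be split or dropped among close paralogs, which makes single values of such families (Ifit, Oas, Gbp, Pira, Gsta, class II genes) less certain. All 9 columns matched 1 sample each by name. Of 54532 gene IDs 54409 had a symbol in the gene name table and 123 did not. Those 123 took 0.0245% to 0.0284% of the reads of a library. Coordinates come from GENCODE vM21 on the same build as mm10. The table holds no entry for unassigned reads.

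Counts were used as deposited. Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 14264; 28653 genes had 0 reads in every library. Library sizes were scaled with TMM and all 9 libraries were fitted together with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with group as the only factor, because the groups are 1 cell type grown by 1 protocol and share an estimate of the spread. The common biological coefficient of variation was 0.179. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are CPM with TMM-adjusted library sizes, given as mean ± SD over 3 libraries. Totals of 24830149 to 35143629 reads put a gene of 1 CPM at about the reads seen for Acod1 in WT_CTR (24 to 55 per library), so ratios at that level carry a counting error that is given as a 95% Clopper-Pearson interval; such intervals cover counting error only. Pairs of libraries within a group differed by far more than sampling noise (chi-square per gene 8.31 to 104), so none was counted as a duplicate.

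The 34 gene lists, the tests of genes and lists, the rule for named genes and the alternatives other than the 3 added later were fixed before the data were examined; most tests of explanations were not. Named genes per comparison are Acod1, up to 10 genes each way with the largest log2 fold change among those past 0.05 with a mean of at least 5 CPM, no overlap between the 2 groups and a symbol that is not a predicted locus, and of each list described up to 4 members with the smallest p. Non-overlap alone occurs by chance for 10% of genes with 3 libraries against 3. Under this rule 47 genes were eligible for KO_CTR against WT_CTR, 2631 for KO_4OI against KO_CTR and 2393 for KO_4OI against WT_CTR. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the 34 lists of a comparison, and counts of members past 0.05 are given over all genes tested and adjusted over the list alone. Members without enough reads were not tested. Camera with an estimated correlation and fry were run beside it.

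The pipeline was tested on simulated data drawn from the fitted means, dispersions and library sizes, with 100 genes changed by each fold. Genes were drawn independently, without structure among the libraries of a group, and genes of the lowest levels were not among those changed. For KO_CTR against WT_CTR 75% of 2-fold and 99% of 4-fold changes were recovered over 14006 genes, for KO_4OI against KO_CTR 85% and 100% over 14028, and for KO_4OI against WT_CTR 73% and 100% over 14024. Of the calls 5.95%, 4.15% and 2.81% were false in these comparisons.

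Alternatives were RLE and upper-quartile scaling, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-trend, only the 2 groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and each library left out in turn. After seeing the data 3 more were added: the libraries with Xist reads left out, sex as a covariate, and 1 divergent library of each group left out (WT_CTR replicate 3, KO_CTR replicate 2, KO_4OI replicate 2). The libraries of the last were picked by eye from the component plot and the correlations within groups. By mean correlation alone KO_4OI replicate 3 would have been taken in place of replicate 2. Wild-type cells with 4-OI were not analysed here. Values of 3 list members that the rule would name are not reported here.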

Results

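The data were RNA sequencing counts from 9 libraries of osteoclasts, the multinucleated cells that resorb bone, grown in vitro from mouse bone marrow cells with macrophage colony-stimulating factor at 20 ng/ml and RANKL at 10 ng/ml. There were 3 groups of 3 libraries. WT_CTR was labelled as wild-type and was left unstimulated. KO_CTR was labelled as deficient in Acod1, the gene for the enzyme that makes itaconate from cis-aconitate, and was left unstimulated. KO_4OI had the same genotype label and received 50 µM 4-octyl-itaconate (4-OI), a cell-permeable ester of itaconate, on day 1. All were collected on day 3. The compound was given only to cells labelled Acod1-deficient, so the comparison of KO_4OI with WT_CTR joins the genotype label and the treatment. Totals per library ran from 24830149 counted reads in KO_CTR replicate 2 to 35143629 in WT_CTR replicate 3, and 14264 genes had enough reads to be tested.

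Acod1 (ENSMUSG00000022126, mm10 chromosome 14, 103046977 to 103056573, plus strand) was read first, because it is the targeted gene. Its reads were not lower in the libraries labelled Acod1-deficient. The WT_CTR libraries held 24, 27 and 55 reads, the KO_CTR libraries 60, 86 and 47, and the KO_4OI libraries 135, 168 and 131. Levels were 1.13 ± 0.381 CPM in WT_CTR, 2.43 ± 1.02 CPM in KO_CTR and 5.39 ± 0.761 CPM in KO_4OI (SD, n = 3 each). The difference between KO_CTR and WT_CTR did not pass the threshold (log2 fold change 1.08, SE 0.32, adjusted p = 0.127). Single genes were rerun only with RLE factors, DESeq2, the replicate number as a block and 1 library left out. Over these settings the adjusted p ran from 0.0398 by DESeq2 to 0.464 without WT_CTR replicate 1. The pooled ratio of KO_CTR to WT_CTR was 2.03, with a 95% Clopper-Pearson interval of 1.60 to 2.60 that covers counting error only. KO_4OI exceeded KO_CTR (log2 fold change 1.16, SE 0.30, adjusted p = 0.0103), a call that was lost without KO_CTR replicate 1 (adjusted p = 0.0531, the highest of the same settings, which went down to 4.63e-04). It also exceeded WT_CTR (log2 fold change 2.24, SE 0.31, adjusted p = 1.68e-04). Counts per gene do not show which exons the reads fell on, and the labels do not give the deleted part. Genotype is therefore written as a label in every comparison.

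The libraries also differed in sex and along a direction that followed the groups only in part. WT_CTR replicate 2 and KO_4OI replicate 3 held 10715 and 8764 reads of Xist, the RNA of the inactive X chromosome, and 0 to 4 reads of each of 4 Y-linked genes. The other 7 libraries held 0 Xist reads, so that KO_CTR had no library of this kind. The libraries of WT_CTR, and those of KO_4OI, therefore did not all come from 1 mouse. The first principal component took 54.6% of the variance and set KO_4OI apart from the other groups. The second took 19.2% and ran from 37.4 in WT_CTR replicate 1 and 31.7 in WT_CTR replicate 2 to -57.1 in KO_CTR replicate 2, while WT_CTR replicate 3 (-2.15) lay beside KO_CTR replicates 1 (-0.79) and 3 (2.24).

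**Figure D1:**
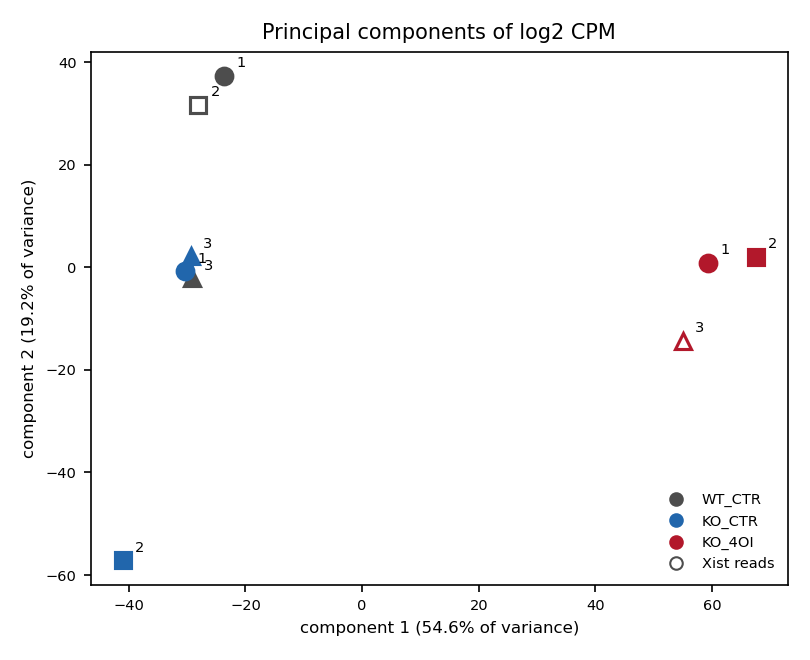
Principal components 1 and 2 of log2 CPM over the 14264 tested genes; each point is a library, colour gives the group, shape and number the replicate, and open symbols mark the 2 libraries with Xist reads. KO_4OI lies apart on component 1, and WT_CTR replicate 3 lies among KO_CTR replicates 1 and 3 on component 2.

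The comparison of KO_CTR with WT_CTR addressed how osteoclasts labelled Acod1-deficient differ from those labelled wild-type. Interferon-stimulated genes, the antiviral genes that interferons switch on, were higher in KO_CTR: 16 of 30 tested rose and 0 fell, and 30 rose when adjusted over the list alone, with a median log2 fold change of 1.28. Camera gave an adjusted p of 1.00e-29, and 0.217 with an estimated correlation. The mean over the list lay above every WT_CTR library in 3 of 3 KO_CTR libraries. How many of the 30 passed rested on single libraries and on the model: 0 did without WT_CTR replicate 1, 1 without WT_CTR replicate 2, 1 without KO_CTR replicate 3 and 22 without WT_CTR replicate 3, and 3 with the replicate number as a block. By DESeq2 26 passed, and 25 did without a low-count filter. The median stayed between 1.16 and 1.40 over the fits without 1 library and was 1.28 with the block. Markers of dendritic cells and antigen presentation lay higher as a list (median 0.88), as did those of macrophages and monocytes (median 0.57) and B cells (median 0.89), and cell cycle genes lay lower (median -0.43). None of these 4 lists passed with an estimated correlation (adjusted p = 0.217, 0.232, 0.217 and 0.232), and 1 of 18, 1 of 23, 0 of 11 and 0 of 35 members passed. The osteoclast function list holds the proteases, proton pump and fusion genes of bone resorption. It had 0 of 23 genes past the threshold in edgeR, limma-trend and DESeq2 (4 at an unadjusted p under 0.05). Without a low-count filter 1 rose and 1 fell. Its median was -0.03, with a sign that depended on the scaling (0.0054 with RLE and 0.06 with upper-quartile factors), and camera's direction was upward (adjusted p = 0.865).

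In all, 74 of 14264 genes changed between KO_CTR and WT_CTR in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 67 higher and 7 lower in KO_CTR. At an unadjusted p under 0.05 there were 2533 genes, where 713 would be expected by chance for independent genes. Another split, which kept most libraries on their labelled sides, reached 3167, so this count does not set the labelled split apart. The count rested on single libraries. It was 0 without WT_CTR replicate 1, 4 without WT_CTR replicate 2 and 247 without WT_CTR replicate 3. It was 21, 112 and 3 without KO_CTR replicates 1, 2 and 3, and 31 and 151 without KO_4OI replicates 1 and 2, which enter through the shared spread. Without WT_CTR replicate 1 edgeR still had 1315 genes at an unadjusted p under 0.05, limma-trend called 0 genes (1287 unadjusted) and DESeq2 89. With all libraries DESeq2 called 603 genes, 446 of them higher. In edgeR with the replicate number as a block 6 genes passed. With sex as a covariate 4 genes passed, and 5 passed without the libraries that held Xist reads, both chosen after seeing the data.

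The libraries of the 2 groups did not overlap for any gene named in this and the next paragraph as among the largest changes. Of the 10 genes with the largest increases under the naming rule, 8 belong to the interferon-stimulated list. Ifit3 (mm10 chromosome 19, 34583531 to 34588731, plus strand), which encodes an antiviral protein with tetratricopeptide repeats, was at 14.8 ± 4.09 against 3.32 ± 0.818 CPM (SD, n = 3; log2 fold change 2.14, SE 0.29, adjusted p = 0.0137). Its neighbours Ifit1 and Ifit2 had log2 fold changes of 1.95 and 1.53. Oasl2, a relative of the 2'-5' oligoadenylate synthetases, was at 24.0 ± 4.84 against 7.56 ± 1.16 CPM (log2 fold change 1.66, SE 0.21, adjusted p = 0.00823). Gbp2, Zbp1, Cxcl10 and Isg15 had log2 fold changes of 1.82, 1.80, 1.62 and 1.56, and among the members with the smallest p were also Mx2 (2.31, from 0.693 ± 0.308 CPM) and Rtp4 (1.24). The remaining 2 were Pira2, a paired immunoglobulin-like receptor (log2 fold change 1.72, SE 0.21, adjusted p = 0.00823), and the GTPase Arl5c (1.66, adjusted p = 0.0496). Pira2 has near-identical relatives, and Ifit, Oas and Gbp genes have close paralogs. Reads may be split or dropped among them, so their values are less certain. Without WT_CTR replicate 1 none of the genes named in this paragraph passed in edgeR. With the replicate number as a block Oasl2, Pira2 and Mx2 passed and the others did not, among them Ifit3, Ifit1 and Ifit2 (adjusted p = 0.0529 each).

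The rule named 5 genes as lower in KO_CTR. Ccl2 encodes a chemokine that attracts monocytes (8.15 ± 0.885 against 19.4 ± 4.88 CPM; log2 fold change -1.25, SE 0.24, adjusted p = 0.0413). Ccnd1 encodes cyclin D1 (53.9 ± 10.5 against 126 ± 11.6 CPM; log2 fold change -1.23, SE 0.22, adjusted p = 0.0290). The others were Ptk2, which encodes focal adhesion kinase (-0.97), the ubiquitin ligase gene Rnf183 (-0.96) and Tubb6, a tubulin gene (324 ± 14.4 against 629 ± 68.1 CPM; -0.96, adjusted p = 0.0285). None of these, nor Itgax and Mertk, passed in edgeR without WT_CTR replicate 1 or with the replicate number as a block. Of 18 dendritic cell and antigen presentation markers 1 rose, the integrin gene Itgax (log2 fold change 0.87, adjusted p = 0.0290), and 15 when adjusted over the list alone (camera adjusted p = 1.63e-11, and 0.217 with an estimated correlation). The class II gene H2-Aa (1.03, adjusted p = 0.0608), Flt3 (1.06) and Cd83 (1.28) did not pass. In DESeq2 12 of the 18 passed. Among 23 macrophage and monocyte markers 1 rose, Mertk, a receptor for the uptake of dying cells (1.28, adjusted p = 0.0496), and 17 when adjusted over the list alone (camera adjusted p = 5.05e-10, and 0.232 with an estimated correlation). Values for Fcgr1, Ms4a7 and Fcgr3 were 0.95, 0.83 and 0.85, none past the threshold. For B cell markers 0 of 11 passed (10 at an unadjusted p under 0.05, 6 by DESeq2) and 10 did when adjusted over the list alone, among them Igkc (1.16) and Cd79b (0.97). Camera gave an adjusted p of 5.67e-09, and 0.217 with an estimated correlation.

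Of 18 lipid handling genes of the liver X receptor list 2 rose, and 7 when adjusted over the list alone (median 0.29, adjusted p = 6.96e-04, and adjusted p = 0.232 with an estimated correlation). Apoe, the apolipoprotein E gene, was at 1502 ± 460.2 against 769 ± 111 CPM (log2 fold change 0.97, SE 0.19, adjusted p = 0.0496). Scd1, a fatty acid desaturase (1.09, adjusted p = 0.0496) rose as well. Neither passed without WT_CTR replicate 1 or with the block. The alternative activation list had 0 of 11 genes past the threshold (7 at an unadjusted p under 0.05, 4 by DESeq2) and 6 adjusted over the list alone (median 0.83, adjusted p = 2.25e-06, and adjusted p = 0.232 with an estimated correlation). Cell cycle genes had 0 of 35 past the threshold (24 at an unadjusted p under 0.05, 2 by DESeq2) and 2 lower adjusted over the list alone, with Mki67 at -0.87 (adjusted p = 0.0875) and Rrm2 at -0.61 (camera adjusted p = 6.43e-11, and 0.232 with an estimated correlation). Heat shock genes had 0 of 16 past it (6 at an unadjusted p under 0.05, 2 by DESeq2), with Hsp90aa1 at -0.85 and Hsph1 at -0.79 (median -0.35, adjusted p = 6.96e-04, and adjusted p = 0.232 with an estimated correlation). In the osteoclast function list the smallest p-values belonged to Acp5, the tartrate-resistant phosphatase gene (0.45, adjusted p = 0.137), Itgav (-0.78), Oscar (0.39) and Dcstamp, a cell fusion gene (-0.48). The p53 list held 1 gene that rose, Gadd45a (1.46, adjusted p = 0.0181), and the T and NK cell list 1, Cd4 (2.32, adjusted p = 0.0232), and both lost the call without WT_CTR replicate 1 and with the block. Further lists past camera's threshold were lysosome and V-ATPase (median 0.22, adjusted p = 0.00244), erythroid (0.59, adjusted p = 6.54e-04), neutrophil (0.28, adjusted p = 0.0179), osteoclast repressor (0.42), inflammatory (0.31), mast cell (0.34), T and NK cell (0.33), ribosomal protein (0.12) and, downward, integrated stress response genes (-0.23). Adjusted p ran from 0.0368 to 0.0395 for the last 6, and was 0.232 to 0.725 with an estimated correlation for all 9. Of these the neutrophil list and the last 6 each lost the call without at least 2 of the 9 libraries in turn, as given with the processing alternatives. By camera with its preset correlation 17 of 34 lists passed, 14 higher and 3 lower in KO_CTR. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05), and fry's directional test passed 9.

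**Figure D2:**
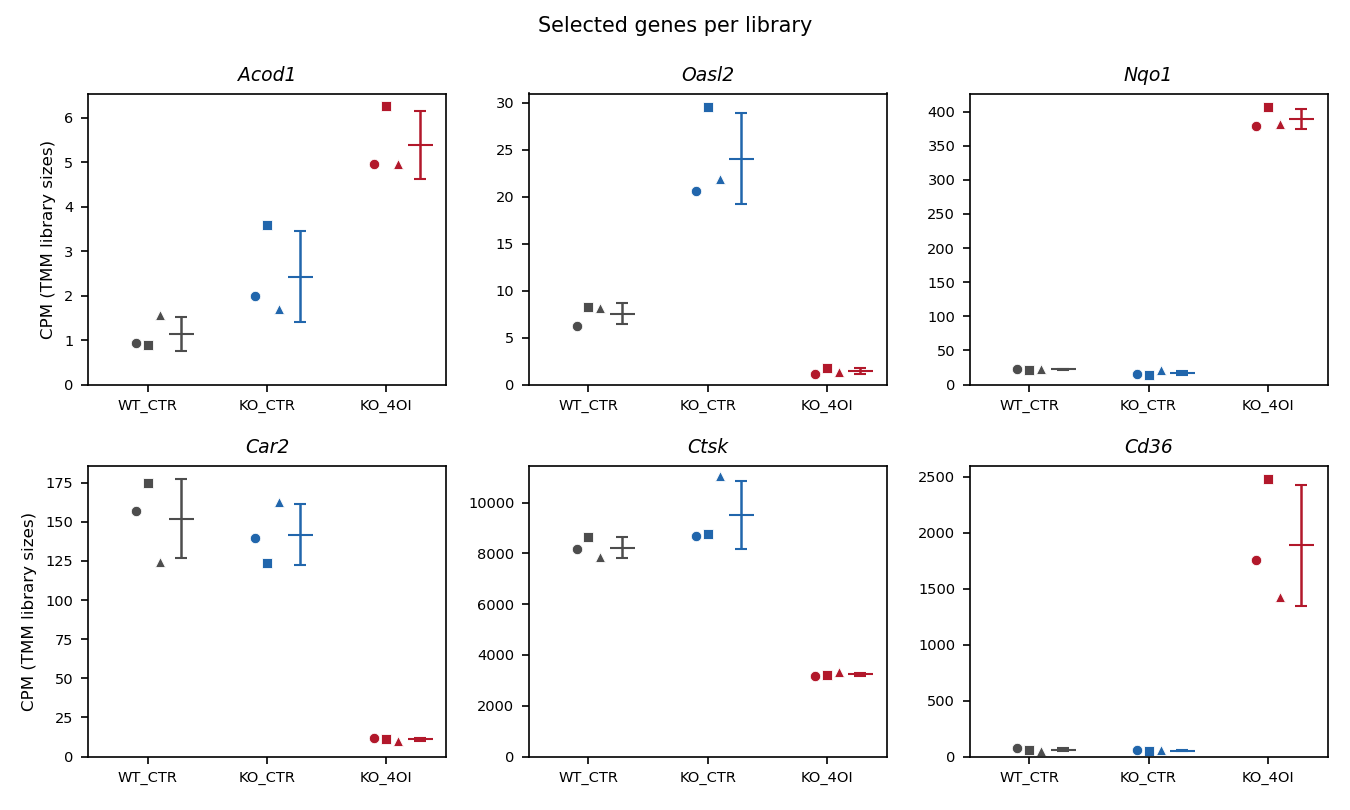
CPM with TMM-adjusted library sizes of 6 genes in each of the 9 libraries; circles, squares and triangles are replicates 1, 2 and 3, and the bar beside each group is the mean with its SD (n = 3). Acod1 is at 0.889 to 1.57 CPM in WT_CTR and at 1.70 to 6.27 CPM in the libraries labelled Acod1-deficient.

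The comparison of KO_4OI with KO_CTR addressed what 4-OI did to osteoclasts labelled Acod1-deficient. Targets of NRF2, the transcription factor of the antioxidant response, rose in 30 of 32 cases, with a median log2 fold change of 2.07, and 20 of 23 cholesterol synthesis genes rose, with a median of 1.27. Osteoclast function genes fell in 20 of 23 cases (median -1.53) and interferon-stimulated genes in 27 of 30 (median -2.39). Respiratory chain genes of the nucleus fell in 39 of 42 cases (median -0.65) and TCA cycle genes in 16 of 21 (median -0.64). In total 3887 of 14264 genes changed, 1856 higher and 2031 lower with 4-OI, and 861 higher and 991 lower by at least 2-fold. Leaving out any 1 library gave 2690 to 3905.

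The 4 NRF2 targets with the smallest p were Prdx1, Nqo1, Gclm and Gsta3. Prdx1, a peroxiredoxin gene, was at 8547 ± 631 against 671 ± 62.7 CPM (SD, n = 3; log2 fold change 3.67, SE 0.13, adjusted p = 1.39e-09). Nqo1, a quinone reductase gene, was at 389 ± 15.4 against 17.1 ± 3.27 CPM (log2 fold change 4.51, SE 0.17, adjusted p = 2.06e-09). Gclm, the modifier subunit of the glutathione synthesis enzyme, was at 1480 ± 118 against 110.5 ± 10.1 CPM (3.74). Gsta3, a glutathione transferase gene with close paralogs, was at 196 ± 19.0 against 2.09 ± 0.826 CPM (6.55). The count was 31 adjusted over the list alone (camera adjusted p = 1.71e-27, and 0.0173 with an estimated correlation). Slc7a11, the cystine transporter gene of this list, was also among the 10 largest increases under the naming rule (5.35, SE 0.25). The largest fitted increase among the named genes was that of Aldh3a1, an aldehyde dehydrogenase gene, with 1834 reads over the KO_4OI libraries and 1 over the KO_CTR libraries, a ratio of 1864 with a counting interval of 334 to 73658. Adh7, an alcohol dehydrogenase gene, had 1967 reads against 6, a ratio of 333 (counting interval 153 to 909). The serpin gene Serpinb9b (7.02), the endothelin receptor gene Ednrb (5.86), the immune receptor gene Tarm1 (5.79), the elastase gene Mmp12 (1055 ± 164 against 23.5 ± 1.47 CPM; 5.49), the adhesion gene Esam (5.44) and the histidine ammonia-lyase gene Hal (5.39) completed the 10, all with adjusted p of 2.01e-07 or less.

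Car2, the carbonic anhydrase gene that supplies protons for bone resorption, had the largest fall of the osteoclast function list, at 11.1 ± 0.967 against 142 ± 19.5 CPM (log2 fold change -3.67, SE 0.18, adjusted p = 1.65e-08). Ctsk, which encodes the collagen-degrading protease cathepsin K, was at 3233 ± 71.8 against 9510 ± 1347 CPM (log2 fold change -1.56, SE 0.12, adjusted p = 1.32e-06). Oscar was at 113 ± 7.09 against 374 ± 44.0 CPM (-1.73) and the integrin gene Itgb3 at 130.0 ± 15.5 against 465 ± 85.7 CPM (-1.84). None of the 23 rose, and 20 fell adjusted over the list alone. Camera gave an adjusted p of 2.12e-14, and 0.0550 with an estimated correlation. In the list of osteoclast transcription factors and signalling 9 of 24 fell and 2 rose, with Prdm1 (-1.76), Jdp2 (-1.73) and Fosl2 (-1.66) lower and Fosl1 higher (3.67, from 0.840 ± 0.277 CPM). The list as a whole did not pass (camera adjusted p = 0.0838). Among 11 tested genes of the osteoclast repressor list 5 rose and 2 fell (camera adjusted p = 0.165). Id1 (1.94) and Rbpj (1.24) were higher and Zfp36l1 (-2.21) and Irf4 (-1.14) lower. Whether each member acts as a repressor in these cells was not tested. Lysosomal and V-ATPase genes moved both ways, 8 of 34 higher and 14 lower, with Ctsl (1.98) and Ctss (1.14) higher and the proton pump gene Atp6v1b2 (-0.86) lower (camera adjusted p = 0.0516).

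Interferon-stimulated genes held 5 of the 10 largest decreases under the naming rule. Rtp4 (mm10 chromosome 16, 23520291 to 23614222, plus strand) was at 0.522 ± 0.0421 against 29.7 ± 6.65 CPM (log2 fold change -5.82, SE 0.25, adjusted p = 6.81e-09). Ifit1 was at 0.371 ± 0.158 against 13.7 ± 3.92 CPM (-5.18), Ifit3 at 0.458 ± 0.235 against 14.8 ± 4.09 CPM (-4.99). Oasl2 was at 1.44 ± 0.317 against 24.0 ± 4.84 CPM (-4.05) and the chemokine gene Cxcl10 was at 1.23 ± 0.339 against 17.3 ± 6.20 CPM (-3.81). All 30 list members fell when adjusted over the list alone (camera adjusted p = 3.93e-22, and 0.126 with an estimated correlation). Of 18 dendritic cell and antigen presentation markers 13 fell and 2 rose, with H2-Aa (-1.94), H2-Eb1 (-2.07), Cd74 (166 ± 15.6 against 685 ± 242 CPM; -2.04) and the class II transactivator gene Ciita (-2.50) lower (median -1.10, adjusted p = 6.25e-05, and adjusted p = 0.290 with an estimated correlation). The other named decreases were Rasgrp1, an activator of Ras (-4.50), the sialyltransferase gene St8sia6 (-4.24), Serpind1, which encodes heparin cofactor II (-3.76), and the keratin gene Krt7 (-3.75, adjusted p = 1.40e-06).

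Cholesterol synthesis genes were led by Sqle, the squalene epoxidase gene, at 98.7 ± 5.22 against 27.1 ± 4.11 CPM (log2 fold change 1.86, SE 0.15, adjusted p = 1.87e-06), Cyp51 (1.69), Fdft1 (1.56) and Acat2 (1.47). Adjusted over the list alone 21 of 23 rose (camera adjusted p = 5.35e-10, and 0.0125 with an estimated correlation). Of 18 lipid handling genes 11 rose and 5 fell. The fatty acid receptor gene Cd36 was at 1888 ± 539.6 against 52.8 ± 6.68 CPM (log2 fold change 5.16, SE 0.24, adjusted p = 1.07e-08). The lipid droplet gene Plin2 was at 1179 ± 29.2 against 297 ± 29.5 CPM (1.99), the lipoprotein lipase gene Lpl at 5688 ± 448 against 1792 ± 517 CPM (1.67) and Mylip had a log2 fold change of 1.23 (median 0.92, adjusted p = 0.00375, and adjusted p = 0.290 with an estimated correlation). TCA cycle genes that fell included Idh3b (-0.88), Mdh2 (-0.95) and Dlst (-0.82), and 1 of 21 rose (camera adjusted p = 1.07e-06, and 0.106 with an estimated correlation). Respiratory chain members that fell included Atp5b (-0.83), Ndufb10 (-0.90) and Uqcrfs1 (-0.96). For that list camera gave an adjusted p of 9.69e-15, and 0.290 with an estimated correlation. Cell cycle genes rose in 11 of 35 cases, among them Pcna (467 ± 8.50 against 229.6 ± 33.8 CPM; 1.02), Ccne2 (0.79) and Rrm2 (0.70), with median 0.43, adjusted p = 3.63e-05, and adjusted p = 0.344 with an estimated correlation.

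Macrophage and monocyte markers rose in 9 of 23 cases and fell in 7, with the scavenger receptor genes Marco (35.5 ± 12.8 against 2.60 ± 0.740 CPM; 3.78) and Msr1 (1.77), Lyz2, the lysozyme gene (19332 ± 3489 against 6063 ± 1051 CPM; 1.67), and Fcgr3 (2.04) higher. The list did not pass (camera adjusted p = 0.296). Neutrophil and granulocyte progenitor markers rose in 4 of 16 cases, the collagenase gene Mmp8 from 81.2 ± 13.5 to 1387 ± 431 CPM (4.10), Ctsg by 0.98, and Mpo and Prtn3 by 0.61 and 0.59. The last 2 did not pass in 4 of the 9 fits without 1 library, with the highest adjusted p without KO_CTR replicate 1 (0.110 for Mpo and 0.115 for Prtn3). That list did not pass either (camera adjusted p = 0.0613). Of the 34 lists 12 passed by camera with its preset correlation, and the NRF2 and cholesterol synthesis lists also did with an estimated correlation.

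**Figure D3:**
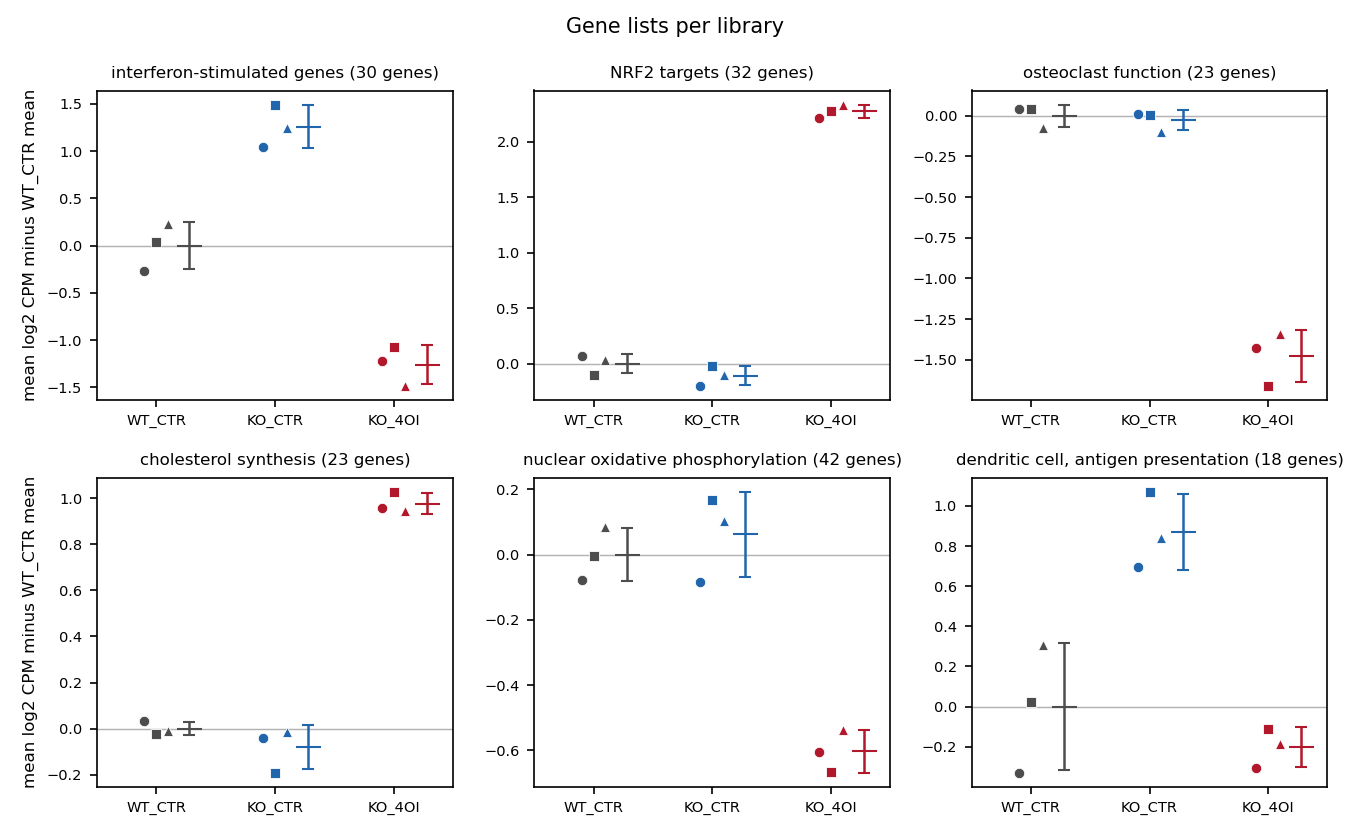
Mean log2 CPM of 6 gene lists in each library, minus the WT_CTR mean; circles, squares and triangles are replicates 1, 2 and 3, and the bar beside each group is the mean with its SD (n = 3). Interferon-stimulated genes lie at 1.04 to 1.49 in KO_CTR and at -1.48 to -1.08 in KO_4OI, and osteoclast function genes lie at -1.66 to -1.34 in KO_4OI.

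The comparison of KO_4OI with WT_CTR addressed how far the treated cells lay from unstimulated osteoclasts labelled wild-type. NRF2 targets were higher in 31 of 32 cases (median 1.99), osteoclast function genes lower in 21 of 23 (median -1.34), and macrophage and monocyte markers higher in 13 of 23 and lower in 1 (median 0.82). Interferon-stimulated genes, which lay above WT_CTR in KO_CTR, lay below it in KO_4OI: 18 of 30 were lower and 0 higher (median -0.94). Altogether 3466 genes differed, 1731 higher and 1735 lower in KO_4OI, and leaving out any 1 library gave 2487 to 4366. By at least 2-fold 998 were higher and 753 lower, and without WT_CTR replicate 3 the counts were 1699 higher and 1342 lower.

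Adh7, Aldh3a1, Ednrb (6.45), Gsta3 (6.09), Esam (5.87), Serpinb9b (5.68), Slc7a11 (5.66), Mmp12 (5.64), Tarm1 (5.47) and Hal (5.23) were the 10 largest increases under the naming rule. Aldh3a1 had 8 reads over the WT_CTR libraries, a ratio of 260 (counting interval 132 to 604), and Adh7 had 7, a ratio of 319 (154 to 794). Rtp4 (0.522 ± 0.0421 against 12.6 ± 1.04 CPM; log2 fold change -4.58, SE 0.25, adjusted p = 3.73e-08) had the largest decrease under the rule. The others of the 10 were the serotonin receptor gene Htr1b (-3.83), Serpind1 (-3.79), Car2 (11.1 ± 0.967 against 152 ± 25.5 CPM; -3.77), Rasgrp1 (-3.65), Ifit1 (-3.23), St8sia6 (-3.23), the placental growth factor gene Pgf (-3.01), Krt7 (-2.94) and Ifit3 (-2.85). In the osteoclast function list Ctsk (-1.35), the fusion gene Ocstamp (111 ± 20.7 against 389.7 ± 25.0 CPM; -1.81) and the calcitonin receptor gene Calcr (16.2 ± 1.44 against 99.2 ± 16.5 CPM; -2.61) were lower, 22 of 23 adjusted over the list alone (camera adjusted p = 3.46e-15, and 0.0459 with an estimated correlation). The NRF2 count was 31 adjusted over the list alone as well (camera adjusted p = 5.52e-30, and 0.0138 with an estimated correlation), with Prdx1 at 3.61, Nqo1 at 4.12 and Gclm at 3.25.

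Oas2 (-2.50), Oasl2 (-2.39) and Ifi27l2a (7.60 ± 0.901 against 38.6 ± 9.33 CPM; -2.34) were among the interferon-stimulated genes below WT_CTR. Adjusted over the list alone 20 were lower and 1 higher (camera adjusted p = 1.58e-08, and 0.346 with an estimated correlation). Lyz2 (19332 ± 3489 against 4086 ± 624 CPM; 2.24), Marco (3.93), Fcgr3 (2.89) and Msr1 (1.77) led the macrophage markers (camera adjusted p = 3.56e-05, and 0.398 with an estimated correlation). Genes of the osteoclast repressor list were higher in 8 of 11 cases and lower in 1 (camera adjusted p = 0.00617, and 0.0894 with an estimated correlation). Irf8 was at 1.58, Id1 at 1.53, Rbpj at 0.85 and Zfp36l1, the lower one, at -1.79. Neutrophil and granulocyte progenitor markers were higher in 8 of 16 cases, with Mmp8 at 4.42 (camera adjusted p = 5.28e-04, and 0.425 with an estimated correlation). Cholesterol synthesis genes were higher in 18 of 23 cases (median 1.10, adjusted p = 4.87e-11, and adjusted p = 0.00911 with an estimated correlation) and lipid handling genes in 9 of 18 (median 0.84, adjusted p = 1.15e-06, and adjusted p = 0.0894 with an estimated correlation). Dendritic cell and antigen presentation markers were higher in 2 of 18 cases, Batf3 (2.99) and Itgax (1.37), and lower in 7, among them Zbtb46 (-1.60) and H2-Eb1 (-1.20). The list did not pass (camera adjusted p = 0.353). TCA cycle genes were lower in 17 of 21 cases and higher in 1 (median -0.63, adjusted p = 8.14e-07, and adjusted p = 0.0894 with an estimated correlation), respiratory chain genes lower in 37 of 42 (median -0.61, adjusted p = 5.89e-13, and adjusted p = 0.346 with an estimated correlation) and p53 targets higher in 6 of 16 (median 0.41, adjusted p = 0.00666, and adjusted p = 0.0894 with an estimated correlation). Osteoclast transcription factors and signalling had 8 of 24 lower and 2 higher (median -0.49, adjusted p = 0.0275, and adjusted p = 0.425 with an estimated correlation), and histones 5 of 8 lower (median -0.58, adjusted p = 0.0162, and adjusted p = 0.241 with an estimated correlation). Glycolysis (adjusted p = 0.0468, and 0.664 with an estimated correlation), B cell (adjusted p = 0.0352, and 0.425) and erythroid lists (adjusted p = 0.0468, and 0.561) passed upward. All 3 lost the call without WT_CTR replicate 1, and each also without at least 1 other library. By camera 16 of 34 lists passed, and 3 with an estimated correlation, those of NRF2 targets, cholesterol synthesis and osteoclast function.

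Whether 4-OI moved the genes that differed between KO_CTR and WT_CTR was read from the genes called in both steps. Of the 74 genes of the first step 59 changed again with 4-OI, 52 in the opposite direction and 7 in the same one. Of the 52, 47 were higher in KO_CTR and then lower with 4-OI. Independent lists of these sizes would share 10.5 genes with opposite and 9.71 with equal direction. Both steps use the KO_CTR libraries with opposite sign, so that opposite directions arise without any effect. In 20 simulations of unchanged groups the correlation of the 2 log2 fold changes across genes was -0.50, against -0.34 observed. Genes are not independent replicates. The covariance was -0.118, against -0.0353 simulated and -0.0497 estimated from the spread of the KO_CTR libraries. Part of the 52 may come from the shared libraries, since 3 libraries cannot be divided into sets of 2. The count of 52 also rested on single libraries, with 0 without WT_CTR replicate 1, 2 without WT_CTR replicate 2, 117 without WT_CTR replicate 3, 19 and 2 without KO_CTR replicates 1 and 3, and 25 and 88 without KO_4OI replicates 1 and 2. With the replicate number as a block it was 5. Of the 67 genes higher in KO_CTR, 26 lay below WT_CTR with 4-OI, 20 above it and 21 did not differ from it past the threshold.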

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

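The alternatives named as chosen after the data were seen are the 2 on sex and the fit without 1 divergent library of each group. No list or named gene past the threshold changed direction in the settings run for it. Between KO_4OI and WT_CTR genes were split almost evenly (1731 higher, 1735 lower), and which side held more turned with the setting, such as 1810 higher and 1622 lower with RLE factors, 1940 and 1783 by DESeq2, 1699 and 1342 without WT_CTR replicate 3, and 1601 and 1707 without KO_4OI replicate 3. The osteoclast function median for KO_CTR against WT_CTR, with 0 genes past the threshold, changed sign with the scaling and in fits without 1 library. The number of genes changed between KO_CTR and WT_CTR (74) was the least stable result. It was 144 with upper-quartile factors, 879 without a low-count filter, 29 at a mean of at least 5 CPM, 603 by DESeq2, 5 without the libraries with Xist reads and 4 with sex as a covariate, and 0 to 247 with 1 library left out. RLE factors (90), limma-trend (58), only the 2 groups compared (61) and a minimum absolute log2 fold change of 1 (60) stayed within 1.5 times. Without 1 divergent library of each group it was 1687. That setting was picked by eye after the data were seen, removes a library that lies apart from the others of its group and so narrows the spread by construction, and leaves 2 libraries per group, so its counts lend no weight to any call. Genes with opposite direction in both steps (52) numbered 96, 413, 19, 268, 3 and 3 under the first 6 of these settings in the same order, 671 without the divergent libraries, and 0 to 117 with 1 library left out. The cause of these shifts was not tested.

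For KO_4OI against KO_CTR a minimum absolute log2 fold change of 1 left 1852 genes, and 1 library left out gave 2690 to 3905. The same settings gave 1751 and 2487 to 4366 for KO_4OI against WT_CTR, and the other settings stayed within 1.5 times in both. Of the 34 lists, camera with an estimated correlation passed 0, 2 and 3 in the 3 comparisons in the order of the report (17, 12 and 16 with the preset), fry's directional test 9, 20 and 18, and fry's mixed test 17, 31 and 31. Without a low-count filter 20 lists passed for KO_4OI against KO_CTR. With 1 library left out the counts were 13 to 16, 11 to 16 and 14 to 17. For KO_CTR against WT_CTR the lists of osteoclast repressors, integrated stress response, inflammatory genes, neutrophils, mast cells, T and NK cells and ribosomal proteins lost the call in some of these fits.

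The replicate number is shared by the 3 groups, and whether it pairs the libraries stays open. Deviations from the group means correlated above 0.1 in 4 of 9 same-numbered pairs (range -0.41 to 0.32). In 9 of 18 cases a library correlated best with its own number, among 3 candidates each. Deviations within a group are tied to each other by construction, so this check cannot exclude a pairing. With the replicate number as a block 6 genes changed for KO_CTR against WT_CTR, 3121 for KO_4OI against KO_CTR and 2871 for KO_4OI against WT_CTR, and 5 genes had opposite direction. At these depths a 2-fold change between KO_CTR and WT_CTR was recovered in 75% of simulated cases, in which genes were independent and libraries held no structure beyond their groups. In the real libraries 2-fold changes may be recovered less often, and smaller differences can go uncalled.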

Other observations

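Tests of 1 library alone, of sex, of shares of cell types, of counting error, of overlapping genes and of the altered allele were chosen only after the data or the results were seen. Those of shares of cell types were changed again after their results were seen. The tests of abundant transcripts and of other splits of the libraries were set before. Members of further lists changed with 4-OI against KO_CTR, and of the lists in this paragraph only that of the unfolded protein response passed camera. Inflammatory genes went both ways, 7 of 23 higher and 7 lower, with Cxcl3 (4.15, from 0.145 ± 0.134 CPM) and Ptgs2 (2.95) higher and Tnfaip3 (-1.45) and Ccl5 (-2.30) lower (camera adjusted p = 0.454). The integrated stress response list was mixed too, 7 of 23 higher and 4 lower, with Atf3 at 168 ± 10.5 against 37.2 ± 15.8 CPM (2.17) and Nupr1 lower (-1.30; camera adjusted p = 0.296), and so was alternative activation, with Egr2 higher (1.82) and Ccl22 lower (-2.05) among 3 of 11 that rose and 4 that fell (camera adjusted p = 0.493). The glucose transporter gene Slc2a1 (146 ± 28.6 against 51.2 ± 6.70 CPM; 1.51) and Pkm (0.88) were among 5 of 19 glycolysis genes that rose (camera adjusted p = 0.0613), and Egln3 (1.68) among 6 of 19 HIF1 targets (camera adjusted p = 0.217). Unfolded protein response genes rose in 7 of 18 cases and fell in 1, with Pdia6 at 0.68 (median 0.46, adjusted p = 0.0350, and adjusted p = 0.290 with an estimated correlation). That list lost the call without KO_CTR replicate 3 (adjusted p = 0.0523), KO_4OI replicate 1 (0.0515) or KO_4OI replicate 3 (0.0624, the highest of the fits without 1 library). p53 targets rose in 9 of 16 cases and fell in 2, with Cdkn1a at 0.80 (camera adjusted p = 0.0518).

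Mitochondrially encoded genes fell in 7 of 15 cases, with mt-Nd2 at -0.58 (median -0.48, adjusted p = 0.00355, and adjusted p = 0.525 with an estimated correlation), and histone genes in 4 of 8, with Hist2h2be at -1.45 (median -0.70, adjusted p = 0.00531, and adjusted p = 0.210 with an estimated correlation). In the itaconate and propionate list 5 of 15 fell and 1, Acod1, rose. Clybl, whose enzyme acts in the breakdown of itaconate, was at 26.2 ± 1.94 against 49.6 ± 4.45 CPM (log2 fold change -0.92, SE 0.14, adjusted p = 3.59e-04), and the carboxylate transporter gene Slc13a3 at 7.24 ± 2.66 against 23.0 ± 8.62 CPM (-1.66), with camera adjusted p = 0.0613. Of 24 fusion and cytoskeleton genes 9 fell and 2 rose, with Cd81 at 2.67 and Myo10 at -1.69 (camera adjusted p = 0.0915). Heat shock (camera adjusted p = 0.236), mast cell (0.902), stromal (0.949), B cell (0.0871), T and NK cell (0.346), erythroid (0.894), ribosomal protein (0.0613), sex-linked (0.493) and substrain lists (0.230) did not pass in that comparison. Of 26 tested genes within 10 Mb of Acod1, 0 differed between KO_CTR and WT_CTR in edgeR and limma-trend and 2 in DESeq2. In edgeR 7 had an unadjusted p under 0.05, beside 2533 of 14264 over all genes tested, and whether the region stands out was not tested.

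With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes as the real one. The real split called 74 genes between KO_CTR and WT_CTR, 3887 between KO_4OI and KO_CTR and 3466 between KO_4OI and WT_CTR, and the highest other split called 0 in each. At an unadjusted p under 0.05 in edgeR the highest other splits had 3167, 2224 and 381 genes, against 2533, 5452 and 4910 in the real ones. The split with 3167 set WT_CTR replicates 1 and 2 with KO_CTR replicate 3 against the other 3 libraries. It was the highest of the other splits and kept most libraries on their labelled sides, so its count includes part of the difference between the labels. The unadjusted counts therefore do not set the labelled split of KO_CTR and WT_CTR apart, and they cannot size a structure that crosses the label.

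Interferon-stimulated genes were higher in each of the 3 KO_CTR libraries than in WT_CTR, and against 1 library or sex as the whole source stand the median log2 fold changes, 1.28 with all libraries, at lowest 1.16 without 1 of the 6 and 1.25 with sex as a covariate (median SE of the members 0.23, 0.27 in the fit with 1.16 and 0.26 with the covariate). The calls themselves ended, with 16 of 30 genes past the threshold at first, 0 without WT_CTR replicate 1 (28 at an unadjusted p under 0.05) and 1 with the covariate (29), while 22 passed without WT_CTR replicate 3, so that the number of libraries alone does not account for the loss, whose cause was not tested. The interferon list rose beyond each of 5 cell type lists without class II genes (median log2 over the list per library). Differences ran from 0.51 (SE 0.063) against B cells to 1.02 (SE 0.21) against neutrophil markers. Lower bounds were smallest against erythroid (0.70, SE 0.21, interval 0.053 to 1.34) and mast cell markers (0.94, SE 0.25, interval 0.23 to 1.66). The 5 comparisons were chosen after results were seen and were not adjusted for their number. With list means the interval against erythroid markers held 0 (-0.035 to 1.37). These unadjusted values go against a lower share of osteoclasts that raised every other cell type alike as the whole source. The erythroid list adds little weight to this, and the reading requires that markers do not change within cells. That condition was not tested. The osteoclast function list itself moved by -0.029 (SE 0.053, mean over the list). A rise of 1 kind of mononuclear cell that carries these genes cannot be told apart from a change within the cells: the interferon list's change exceeded that of the dendritic cell list by 0.39 (SE 0.046), but class II genes respond to interferon themselves and no cell was measured singly. A difference from the genotype label stays open as a hypothesis. The Acod1 reads, which were not lower under that label, cannot settle whether the label holds.

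Acod1 reads were not lower in the libraries labelled Acod1-deficient. Counting error is argued against by the lower bound of the ratio of KO_CTR to WT_CTR, 1.60, and reads of another annotated gene by the number of genes that overlap Acod1 on either strand, 0. A transcript left by the altered allele and exchanged genotype labels cannot be told apart here: 6 of the 6 libraries labelled Acod1-deficient had more Acod1 CPM than every WT_CTR library, and counts per gene do not show exons. A candidate explanation is an allele that keeps a counted transcript, which reads over single exons would test.

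Osteoclast function genes fell with 4-OI, with a median log2 fold change of -1.53. Whether a lower share of osteoclasts raised every other cell type alike cannot be decided here. Changes of 5 cell type lists without class II genes ran from 0.35 for macrophage to -0.25 for B cell markers (median log2 over the list per library). Their difference of 0.60 (SE 0.098) sets the largest change against the smallest, and its SE does not allow for that choice. The interval of each of the 5 changes held 0, and 0 of their 10 pairs passed a Bonferroni adjustment. Reading the changes as shares also requires that markers do not change within cells, which was not tested. The fall is not accounted for by a few abundant transcripts, with a median of -1.37 over the 19 members left when the 50 most abundant genes were removed and upper-quartile factors used. Nor is it by sex, with a median of -1.48 without the libraries with Xist reads. A shift in the kind of macrophage present, or fewer cells completing differentiation, stays open and was not tested.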
